A study of Mus musculus with 8 samples.

How the data were processed

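RNA was extracted with Trizol and enriched for polyadenylated transcripts before library construction, per the labels' protocols, which do not say whether the kit kept strand. The 4 Control and 4 LMF libraries are named by codes in the sample titles. All 8 carry the same treatment entry in another label field, so the groups were taken from the titles. The labels do not say whether the libraries of a group came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. A group given magnetic rod-shaped micromotors, which the series' design names, was not analysed here.

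Per the submitters' processing notes, the tools were Trimmomatic, HISAT2 2.0.5, HTSeq and DESeq2 and the genome build was mm10, with no role or order given. The deposited table holds raw read counts per gene and library, and the authors' FPKM values beside them, with 55880 rows of which 464 carry an XLOC identifier and no Ensembl ID. Only 1543 of the 52135 Ensembl IDs matched to GENCODE M21 have that mm10 annotation's start and end. The coordinates were taken to be those of GRCm39 from scaffold names, which 2 rows carry, and were not compared with a GRCm39 annotation. Coordinates are therefore given as the table has them, and M21 was used for gene type and GC content only. The deposited FPKM divides by a gene length that equals the listed length for 22.1% of the 16070 genes with a count in every library, and by the summed counts of the library. Every column of per-sample values was mapped to a sample.

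The main test was edgeR 4.0.16's quasi-likelihood F test (robust, group as the only term) in R 4.3.3 on the deposited counts, after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment over the 14074 tested genes at 0.05. Standard errors are the absolute log2 fold change over the square root of F. CPM are counts scaled to a common library total after TMM. The common biological coefficient of variation was 0.0661 and the median log2 fold change was near 0, with 6 residual degrees of freedom. The 25 gene lists and 13 marker lists were fixed before the data were examined, and 789 of their 790 members were found in the table. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 38 lists. Of the 17 lists called, 4 were also called with a correlation estimated per list: NF-kappaB, inflammatory cytokines, unfolded protein and integrated stress response, and actin cytoskeleton. The signs of median, mean and test differed for LXR and PPAR-gamma, type 1 dendritic cell, B cell, erythroid and mechanosensitive channel lists, none of which passed.

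Genes were named by a rule fixed before the data were examined. It takes the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 2 and no overlap between groups, leaving out unnamed gene models, then the 3 called members with the smallest adjusted p of each list, or the 1 member with the smallest adjusted p, called or not, where fewer than 3 were called, and 13 genes fixed by name. It gave 125 tested genes, of which the text prints a part, and Yap1, which had too few counts. Genes named outside the rule are said to be so.

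Library pairs were compared by chi-square per degree of freedom over genes with at least 20 counts in the pair. It was 3.50 to 7.80 within groups and 26.6 to 35.2 between groups, so no pair looked like copies of 1 library, which does not show that the libraries came from separate cultures. Depth per library was 16592672 to 21585750 counts. On simulated counts for this comparison, over the 14074 genes, the same test recovered 38% of 50 genes changed 1.25-fold, 70% at 1.5-fold, 90% at 2-fold and 96% at 4-fold, and called 10 of 13688 unchanged genes.

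Alternatives fixed before the data were examined were DESeq2 (1.42.0) size factors, upper-quartile factors and library size alone, the DESeq2 test, limma-voom with sample weights, no filter on low counts, CPM of 1 in 4 libraries, the replicate number as a block, leaving out each library, a test against a 1.5-fold change, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and protein-coding genes only. For the lists they were an estimated correlation, fry, DESeq2 size factors, the CPM filter, the block and leaving out each library. Offsets for GC content and gene length in 20 bins each were chosen after seeing the data. All 35 splits of the libraries into 4 and 4 were also fitted.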

Results

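Gene expression was measured by RNA sequencing in mouse bone marrow-derived dendritic cells, antigen-presenting cells grown from bone marrow in culture. The cells came from male wild-type C57BL/6 mice aged 6 weeks and were kept for 6 days with 10 ng/mL interleukin-4 and 20 ng/mL GM-CSF. The 8 libraries form 2 groups of 4. Cells of the LMF group were incubated for 24 h with ITRs and then exposed to a low-frequency magnetic field (LMF). The labels leave the name ITR unexplained, and the series title speaks of an intracellular magnetic torque-regulator. Control cells were untreated, and the RNA was taken 6 h after treatment. The comparison of LMF with Control shows how gene expression differed between treated and untreated dendritic cells. Mechanical stimulation cannot be told apart in it from other effects of the ITRs or the field. The comparison takes the ITRs and the field together, because no group with only one of them was analysed here. The summed gene counts were 17309368 to 21585750 in the Control libraries and 16592672 to 18532878 in the LMF libraries. Of all genes, 14074 had enough counts to be tested.

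Many genes of inflammation rose in LMF and several macrophage markers fell. Cxcl2, a chemokine that attracts neutrophils, had the largest increase among the genes named by the fixed rule, from 8.94 ± 0.388 CPM in Control to 165 ± 24.8 CPM in LMF (mean ± SD, n = 4 each), a log2 fold change of 4.21 ± 0.14 (SE). Cxcl10, an interferon-inducible chemokine, rose by 4.11 ± 0.16 and Tnf, the cytokine tumour necrosis factor, by 3.56 ± 0.09. Cxcl3 rose by 3.37 ± 0.08 and Acod1, the enzyme that makes itaconate, by 3.18 ± 0.06. On the other side, Apoe, the lipid carrier apolipoprotein E, fell from 3162 ± 206 to 1302 ± 83 CPM (log2 fold change -1.28 ± 0.05). Ccr2, the receptor for the monocyte chemokine Ccl2, fell from 752 ± 28.6 to 335 ± 9.13 CPM (-1.17 ± 0.04). Coordinates are the table's own, which were taken to be those of GRCm39. Cxcl2 (ENSMUSG00000058427) lies on chromosome 5 from 91051730 to 91053797, Tnf (ENSMUSG00000024401) on chromosome 17 from 35418357 to 35420983, and Apoe (ENSMUSG00000002985) on chromosome 7 from 19430034 to 19433113.

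Across all genes, 4845 of the 14074 passed the edgeR quasi-likelihood test at an adjusted p of 0.05, 2464 higher and 2381 lower in LMF. Of the called genes 3509 had an absolute log2 fold change under 0.5. At the other end 387 changed at least 2-fold, 256 upwards and 131 downwards. On the deposited FPKM with limma-trend this count was 113 with a pseudocount of 1 (85 upwards, 28 downwards) and 199 with 0.1. In 31.8% of the tested genes the 4 LMF libraries lay entirely on one side of the 4 Control libraries, where chance gives 2.86%. On the second principal component, with 10.7% of the variance, LMF replicate 4 lay at -27.2 and the other LMF libraries at 6.79 to 14.03. Without LMF replicate 4, 4425 genes were called. The count was 4307 to 5047 over all fits without 1 library, and the highest was without LMF replicate 1. Against a fold change of 1.5 the same model called 363 genes, 240 higher and 123 lower. Values with ± and no unit are log2 fold changes of LMF against Control with their SE (n = 4 each). The 10 largest increases under the naming rule also included Plk2, a stress-induced kinase, at 3.14 ± 0.15, and Clec4e, a receptor for damaged cells and mycobacterial lipid, at 2.88 ± 0.05. The rest were Rasgef1b at 2.59 ± 0.11, the receptor Gpr84 at 2.58 ± 0.12 and Inhba, a subunit of activin A, at 2.44 ± 0.09. Plk2 was measured at 243 CPM in LMF replicate 1 and at 345 to 348 CPM in the other LMF libraries. The 10 largest decreases were Plxna4os1 (-1.51 ± 0.17), Apcdd1 (-1.48 ± 0.17), Engase (-1.45 ± 0.10), Cbx8 (-1.38 ± 0.16), Thbd (-1.36 ± 0.15), Gpr34 (-1.33 ± 0.13), Apoe, C5ar2 (-1.26 ± 0.13), Zfp395 (-1.25 ± 0.10) and Ypel2 (-1.22 ± 0.08). Plxna4os1 overlaps Plxna4 and Gpr34 overlaps Cask on the opposite strand, so that the values of both are uncertain where the counting ignored strand. Jun, Cd274, Ndufs3 and Trim16, named further on, also overlap other counted genes. By Dixon's test 1 library lay apart from the other 3 of its group for Engase, Atf3, Hspa5, Ppp1r15a, Hsp90aa1, Fas, Cd274, Hmgcs1, Kit, Ndufs3, Hexa, Clec10a, Plk2, Ccr7, Cd14 and Ear2. In all 17 of 258 groups were flagged, where chance gives about 12.9, so many of these flags may be chance.

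**Figure D1:**
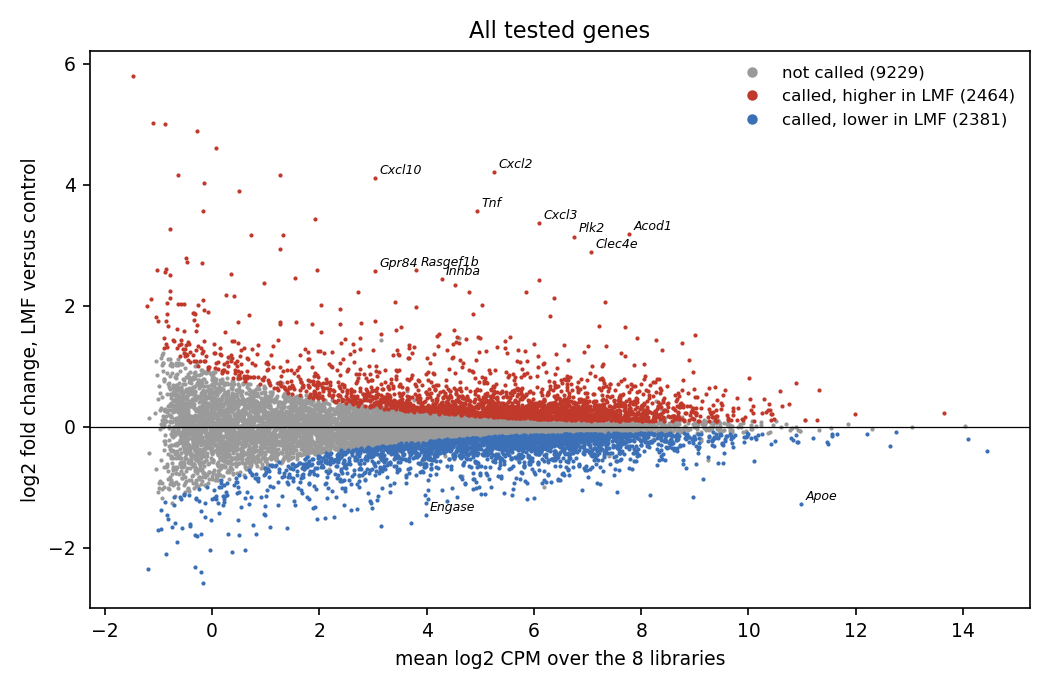
Each point is a tested gene, placed by its mean log2 CPM over the 8 libraries (x axis) and its log2 fold change of LMF against Control (y axis), red for the 2464 genes called higher, blue for the 2381 called lower and grey for the rest. The 10 largest increases that the rule named lie between log2 fold changes of 2.44 and 4.21, and Apoe lies at -1.28.

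All 24 tested genes of the NF-kappaB pathway and its feedback list rose (camera adjusted p = 9.37e-20, adjusted p = 0.0229 with an estimated correlation). Sod2, mitochondrial superoxide dismutase, rose by 1.65 ± 0.04, and the feedback inhibitors Tnfaip3 by 1.23 ± 0.04 and Nfkbie by 1.20 ± 0.05. Of 16 inflammatory cytokines 12 rose, 1 fell and 3 did not pass (camera adjusted p = 8.7e-08, adjusted p = 0.0278 with an estimated correlation). Il1b, interleukin-1 beta, rose from 12.8 ± 1.72 to 59.9 ± 5.93 CPM (2.23 ± 0.08), Il6 from 4.10 ± 0.692 to 7.76 ± 1.24 CPM (0.92 ± 0.16) and Il12b, a subunit of interleukin-12, from 72.2 ± 4.52 to 99.5 ± 6.08 CPM (0.46 ± 0.05). Of 18 chemokines 11 rose, 3 fell and 4 did not pass (camera adjusted p = 5.47e-05), a call not kept with an estimated correlation (adjusted p = 0.164). Cxcl1 rose by 4.15 ± 0.24 from 0.537 CPM, a low level, and Ccl4 by 1.98 ± 0.12. Immediate early genes, sampled here 6 h after treatment, had 20 of 25 members higher and 2 lower (camera adjusted p = 5.74e-08, adjusted p = 0.0575 with an estimated correlation). Jun was at 1.06 ± 0.06, Atf3 at 0.80 ± 0.05 and Junb at 0.59 ± 0.04. Junb overlaps Prdx2 on the opposite strand. Of 30 type I interferon response genes 24 rose and none fell (camera adjusted p = 1.9e-07, adjusted p = 0.124 with an estimated correlation). Isg15 was at 1.47 ± 0.14, Rsad2 at 1.27 ± 0.10 and Ifit1 at 1.27 ± 0.12. Of 26 pattern recognition genes 12 rose and 8 fell (camera adjusted p = 0.140), with Clec4e and Tlr2, the lipoprotein receptor (1.43 ± 0.04), among the higher ones. Adjusted over the list alone, the counts were 21 higher and 2 lower for immediate early genes, 24 and 1 for interferon genes and 13 and 9 for pattern recognition, and as above for the NF-kappaB, cytokine and chemokine lists.

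**Figure D2:**
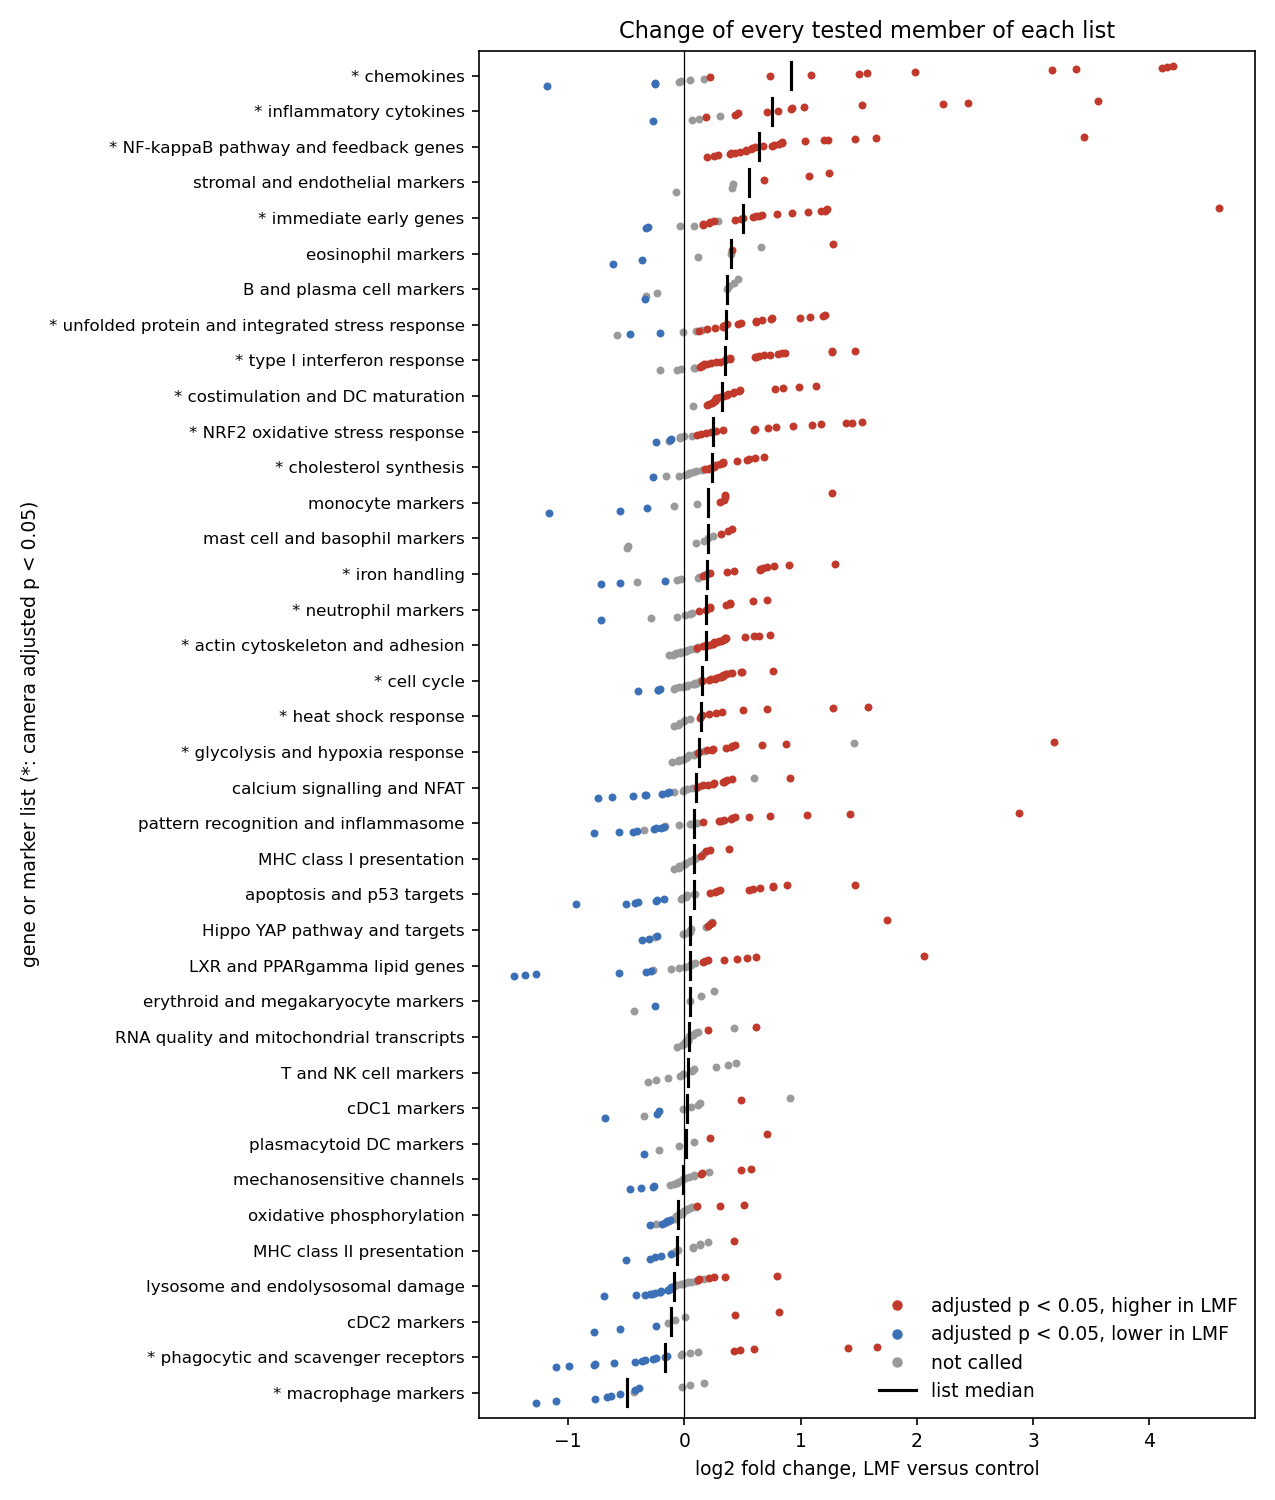
Each row is one of the 38 gene and marker lists, and each point a tested member at its log2 fold change of LMF against Control (x axis), red or blue where it was called higher or lower and grey where it was not. Black bars are list medians, and a star marks the 17 lists with a camera adjusted p under 0.05. The highest median, 0.91, belongs to the chemokines and the lowest, -0.49, to the macrophage markers.

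Nearly all genes of dendritic cell maturation rose. Of 22 tested genes of costimulation and dendritic cell maturation 21 rose and none fell, with the same count adjusted over the list alone (camera adjusted p = 3.3e-08), and the call was not kept with an estimated correlation (adjusted p = 0.168). Cd40, the receptor for T cell help, rose from 18.0 ± 2.14 to 35.7 ± 0.969 CPM (0.98 ± 0.08), Cd274, the ligand of PD-1, by 0.47 ± 0.04, Cd86 by 0.38 ± 0.05 and Cd80 by 0.27 ± 0.06. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 0.25 ± 0.05 from an already high 1182 ± 54.9 CPM. LMF replicate 1, at 1586 CPM, lay above the 1341 to 1351 CPM of the other LMF libraries. In that replicate the list lay a median of 0.18 (log2) above the mean of the other LMF libraries. The lists of antigen presentation did not pass camera, and both passed fry, which does not compare a list with other genes (class I higher, adjusted p = 0.0153, and class II lower, adjusted p = 0.0104). In MHC class I presentation 4 of 17 genes rose and none fell, with the same count adjusted over the list alone (camera adjusted p = 0.0956), and the list passed without LMF replicate 3 (adjusted p = 0.0367). Among the 4 were the folding proteins Calr (0.39 ± 0.04), Pdia3 (0.22 ± 0.04) and Canx (0.19 ± 0.04). H2-K1, a class I heavy chain that belongs to a family of near-identical copies, had a log2 fold change of 0.05 ± 0.04 (adjusted p = 0.28, edgeR) and did not pass. In MHC class II presentation 1 of 14 genes rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.392). H2-DMa was at -0.50 ± 0.04, where Brd2 overlaps on the opposite strand, Lgmn at -0.30 ± 0.03 and the protease Ctss at -0.25 ± 0.04. H2-Ab1, a class II chain, had a log2 fold change of -0.07 ± 0.04 (adjusted p = 0.20) and did not pass, and with offsets for GC content and length, chosen after seeing the data, its sign turned (log2 fold change 0.0156, not called). In LMF replicate 1 the class II list lay a median of 0.12 (log2) above the other LMF libraries.

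Stress programmes rose in several lists. Of 24 oxidative stress genes under the transcription factor NRF2 16 rose and 3 fell (camera adjusted p = 3.3e-06, adjusted p = 0.214 with an estimated correlation). Hmox1, heme oxygenase 1, rose from 304 ± 11.2 to 875 ± 41.4 CPM (1.52 ± 0.04), Slc7a11, the cystine transporter, by 1.39 ± 0.04 and Txnrd1 by 1.10 ± 0.04. Of 24 genes of the unfolded protein and integrated stress responses 18 rose and 2 fell (camera adjusted p = 6.89e-06, adjusted p = 0.0278 with an estimated correlation). Those that rose included Ppp1r15a (0.74 ± 0.05), Slc3a2 (0.62 ± 0.04) and the ER chaperone Hspa5 (0.61 ± 0.04). Of 17 heat shock genes 10 rose (camera adjusted p = 0.00561, adjusted p = 0.109 with an estimated correlation), among them Hsp90aa1 at 0.71 ± 0.05. Of 21 iron handling genes 12 rose and 3 fell (camera adjusted p = 0.00125, adjusted p = 0.174 with an estimated correlation). Lcn2, an iron-siderophore binder that is also among the neutrophil markers, rose by 0.71 ± 0.04. The transporters Slc11a1 and Slc25a37 rose by 0.68 ± 0.04 and 0.65 ± 0.04. Of 25 apoptosis and p53 targets 11 rose and 7 fell (camera adjusted p = 0.207), with Fas at 0.65 ± 0.05 and Sesn1 at -0.94 ± 0.06. In the lysosome and endolysosomal damage list 6 of 33 genes rose and 14 fell (camera adjusted p = 0.140). The autophagy receptor Sqstm1 was at 0.80 ± 0.03, Trim16 at -0.69 ± 0.09 and Hexa at -0.29 ± 0.04. Adjusted over the list alone, the lysosome counts were 9 and 17, and the counts of the other lists here were as given.

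Among genes linked to force, the cytoskeleton list rose while the channels went both ways. Of 35 actin cytoskeleton and adhesion genes 21 rose and none fell (24 and 1 adjusted over the list alone, camera adjusted p = 1.07e-05, adjusted p = 0.0278 with an estimated correlation). The integrin subunit Itga5 was at 0.60 ± 0.05, the nuclear lamin Lmna at 0.52 ± 0.05 and the myosin heavy chain Myh9 at 0.35 ± 0.03. Of 19 mechanosensitive channel genes 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.878). The volume-regulated channel subunit Lrrc8c rose by 0.57 ± 0.05 and Panx1 by 0.49 ± 0.06, and Trpv2 fell (-0.27 ± 0.04). Piezo1, a stretch-gated channel, was 111 ± 5.06 CPM in Control and 123 ± 7.03 CPM in LMF (0.15 ± 0.05, adjusted p = 0.013). It overlaps Ctu2 on the opposite strand, and did not pass without Control replicate 4 (adjusted p = 0.0881), without LMF replicate 4 (0.0747) or on log2 FPKM (0.0755). Yap1, a force-responsive transcription cofactor, had 2 to 14 counts per library and was not tested. Of 15 tested genes of the Hippo YAP pathway 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.523). Axl was at -0.37 ± 0.04, Vgll4 at -0.30 ± 0.06 and Lats1 at 0.22 ± 0.05. Of 27 calcium signalling and NFAT genes 11 rose and 8 fell (13 and 8 adjusted over the list alone, camera adjusted p = 0.489), with the store-operated channel Orai1 at -0.62 ± 0.06 and Calm2 at -0.34 ± 0.04.

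Some genes of the cholesterol synthesis list and of the glycolysis and hypoxia list rose, and other members did not pass. Of 24 cholesterol synthesis genes 15 rose and 1 fell (camera adjusted p = 8.98e-05, adjusted p = 0.0575 with an estimated correlation). Hmgcs1, a synthase of the pathway, was at 0.46 ± 0.05. Of 25 glycolysis and hypoxia genes 12 rose and none fell (camera adjusted p = 1.41e-04, adjusted p = 0.161 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, was at 0.87 ± 0.05 and Hif1a at 0.67 ± 0.04. The list median was 0.12, and the list includes Acod1, the itaconate enzyme, at 3.18 ± 0.06. The KEGG pathway of glycolysis and gluconeogenesis, looked at after its values were seen, had 11 of 44 genes higher and 8 lower (camera adjusted p = 0.723). Of 22 lipid genes under LXR and PPAR-gamma 8 rose and 6 fell (camera adjusted p = 0.791), with Acsl1 at 2.06 ± 0.04 opposite Apoe and Cpt1a (-0.56 ± 0.05). Of 33 oxidative phosphorylation genes 3 rose and 5 fell (camera adjusted p = 0.325), with Cycs at 0.52 ± 0.06 and Ndufs3 at -0.29 ± 0.06. Of 35 cell cycle genes 16 rose and 4 fell (camera adjusted p = 0.00255, adjusted p = 0.406 with an estimated correlation). Those that rose included Hmgb2 (0.36 ± 0.04), the replication clamp Pcna (0.41 ± 0.04) and the nucleotide-synthesis subunit Rrm2 (0.76 ± 0.08). Adjusted over the list alone, the counts were 15 and 0 for glycolysis, 3 and 4 for oxidative phosphorylation, 17 and 4 for the cell cycle, and as given for the other 2 lists.

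The macrophage markers had the lowest median of the 38 lists, -0.49. Of 12 tested macrophage markers 8 fell and none rose, also adjusted over the list alone (camera adjusted p = 5.47e-05, adjusted p = 0.167 with an estimated correlation). Mertk, a receptor for dying cells, fell from 63.4 ± 3.51 to 29.6 ± 2.81 CPM (-1.10 ± 0.07) and C1qc, a complement subunit, fell by 0.67 ± 0.05 on the log2 scale, beside Apoe. In LMF replicate 1 the macrophage list lay a median of 0.11 (log2) below the other LMF libraries. Of 21 phagocytic and scavenger receptors 12 fell and 5 rose, also adjusted over the list alone (camera adjusted p = 0.0439, adjusted p = 0.69 with an estimated correlation). Fcgr4, an immunoglobulin receptor, was at -0.99 ± 0.07 and Olr1, a receptor for oxidised LDL, at 1.40 ± 0.09. This call was not kept without Control replicate 2 (adjusted p = 0.0568), without LMF replicate 1 (adjusted p = 0.18) or with a filter of CPM of 1 in 4 libraries (adjusted p = 0.0577). Of 15 neutrophil markers 9 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.214 with an estimated correlation), among them Mpo (0.59 ± 0.06) and Elane (0.39 ± 0.05). Of 10 monocyte markers 5 rose and 3 fell (camera adjusted p = 0.489), with Hp at 1.27 ± 0.04 opposite Ccr2 and Fn1 (-0.56 ± 0.05).

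The remaining marker lists did not pass the camera test. Of 10 markers of type 1 dendritic cells 1 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.707), with Flt3 at 0.49 ± 0.07 and Clec9a, which overlaps Clec1b, at -0.68 ± 0.12. Of 8 markers of type 2 dendritic cells 2 rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.481), with Clec10a at -0.78 ± 0.09. Of 6 plasmacytoid markers 2 rose and 1 fell (camera adjusted p = 0.781). Of 9 mast cell and basophil markers 3 rose (camera adjusted p = 0.0956), among them Kit at 0.32 ± 0.06. Of 7 eosinophil markers 2 rose and 2 fell (camera adjusted p = 0.780). None of 10 T and NK cell markers passed (camera adjusted p = 0.781), the nearest being Lck at 0.37 ± 0.22 (adjusted p = 0.19). Of 7 B cell markers 1 fell, Ighm at -0.34 ± 0.06 (camera adjusted p = 0.961). Of 5 erythroid and megakaryocyte markers 1 fell (camera adjusted p = 0.858), Pf4 at -0.25 ± 0.08. Pf4 lost its call when any of Control replicates 1, 2 and 4 or LMF replicates 1 and 4 was left out (adjusted p up to 0.140). Of 6 stromal and endothelial markers 3 rose (camera adjusted p = 0.0735), and the list passed without Control replicate 2 (adjusted p = 0.0329) or LMF replicate 4 (adjusted p = 0.0303). Kdr, an endothelial receptor among the 3, was low, at 2.48 ± 0.277 CPM in Control and 5.90 ± 0.861 CPM in LMF. Of the other called members, Pdgfrb lost its call without Control replicate 1, 2 or 4 or LMF replicate 1, 2 or 3 (adjusted p up to 0.127), and Col1a2 without Control replicate 1 (adjusted p = 0.0718). Adjusted over the list alone, the counts of the lists with one count given here were the same. Of 14 tested transcripts of the RNA quality and mitochondrial list 2 rose (camera adjusted p = 0.247), among them Neat1, a nuclear long noncoding RNA, at 0.62 ± 0.06. Mitochondrial genes took 2.79 ± 0.141% of counts in Control and 2.81 ± 0.127% in LMF (SD, n = 4 each, two-sided exact permutation p = 0.714). Ribosomal protein genes took 3.36 ± 0.057% and 2.99 ± 0.206% (two-sided exact permutation p = 0.0286, the smallest the design allows, adjusted 0.0571 over 4 such measures). The 10 most counted genes of each library took 10.97 ± 0.223% and 10.06 ± 0.204% (two-sided exact permutation p = 0.0286, adjusted 0.0571), and the total counts gave p = 0.286 (exact permutation, adjusted 0.381).

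**Figure D3:**
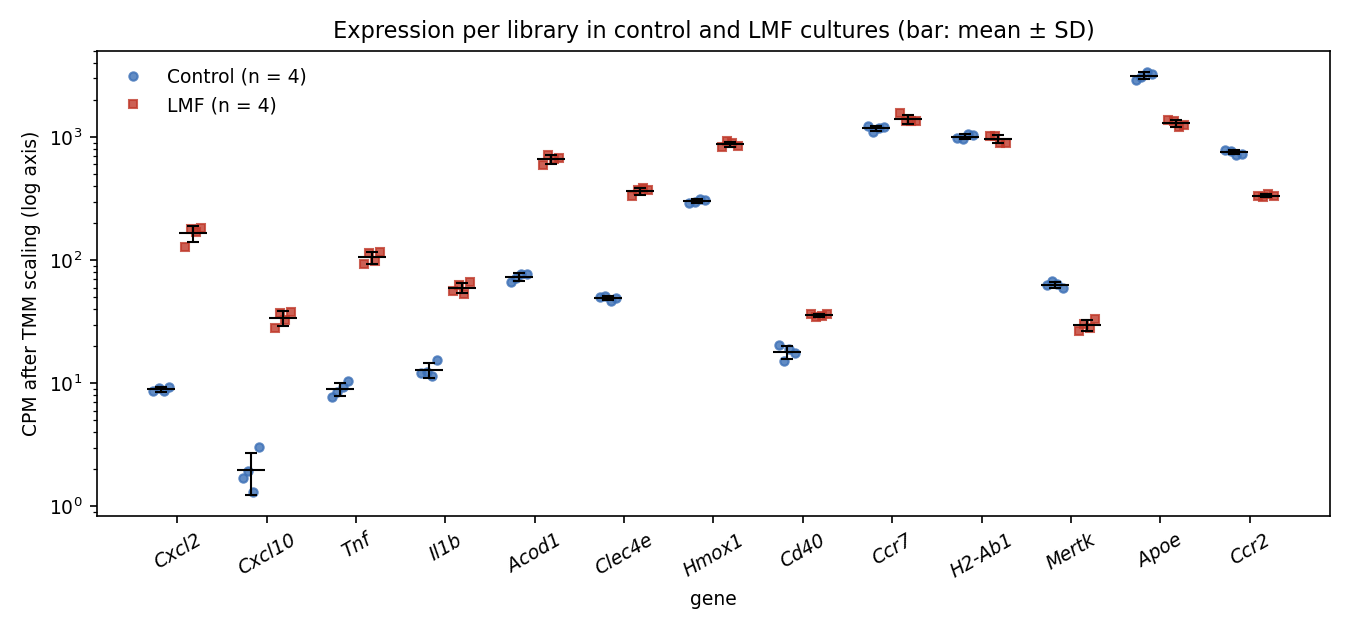
CPM after TMM scaling (log axis) for 13 genes, with blue circles for the 4 Control and red squares for the 4 LMF libraries and black bars for the mean ± SD. Cxcl2 lies at 8.94 CPM in Control and 165 CPM in LMF, the groups overlap for H2-Ab1, and Apoe, Mertk and Ccr2 are lower in every LMF library than in every Control library.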

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

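The test of depth and RNA quality and the test of maturity markers for LMF replicate 1 were chosen after the result was seen. In 17 of the 258 groups of 4 libraries looked at, 1 library lay far from the other 3 by Dixon's test at 95%. Chance flags about 1 in 20 groups, here 12.9. Of the 17, 7 were in LMF replicate 2, 5 in LMF replicate 1, 2 in Control replicate 1 and 1 each in Control replicates 2, 3 and 4.

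In LMF replicate 1, Plk2 was measured at 243 CPM (345 to 348 CPM in the other LMF libraries), Atf3 at 183 CPM (209 to 213), Hspa5 at 847 CPM (951 to 970), Ccr7 at 1586 CPM (1341 to 1351) and Engase at 11.5 CPM (8.68 to 9.01). In LMF replicate 2, Ppp1r15a was measured at 110.2 CPM (106 in the other LMF libraries), Fas at 97.7 CPM (108 to 109), Cd14 at 596 CPM (560.0 to 565), Kit at 53.3 CPM (58.6 to 59.2), Ndufs3 at 49.8 CPM (43.8 to 44.6), Hexa at 604 CPM (565 to 569) and Clec10a at 15.1 CPM (13.01 to 13.3). Among the Control libraries, Hsp90aa1 was at 171 CPM in replicate 4 (175 to 176 in the others), Cd274 at 209 CPM (201) and Hmgcs1 at 106 CPM (94.4 to 95.8) in replicate 1, Hexa at 725 CPM (698 to 702) in replicate 3 and Ear2 at 11.1 CPM (12.5 to 12.7) in replicate 2.

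LMF replicate 1 differed from the other LMF libraries in the size of its changes, while LMF replicate 4 lay apart on the second principal component (-27.2, with 6.79 to 14.03 for the other LMF libraries, 10.7% of the variance), for which no explanation was tested. For LMF replicate 1, low depth is argued against, since its total of 17.814 M counts lies within the 16.593 M to 21.586 M of the other 7 libraries. Its mitochondrial share of 2.63% lies within their 2.587 to 2.913% but below the 2.822 to 2.913% of the other LMF libraries. Its ribosomal protein share of 3.231% lies above the 2.793 to 3.092% of the other LMF libraries. Poor RNA stays open, because neither share measures RNA integrity. A weaker response as a whole may account for its smaller changes: over genes called without this library, the slope of its changes on those of the other LMF libraries was 0.841 ± 0.0098 (bootstrap SD) among higher and 0.807 ± 0.0166 among lower genes, against 0.973 to 0.994 and 0.883 to 0.905 for the other LMF libraries. More mature dendritic cells may also have a part. The costimulation list lay a median of 0.18 (log2, bootstrap SD 0.034) above the other LMF libraries, the class II list 0.12 above and the macrophage list at -0.1085 (bootstrap SD 0.034). The bootstrap SDs of slopes and medians are over genes, which are not independent replicates. They do not measure the spread between cultures. The costimulation list rose in LMF and the macrophage list fell, so by their medians this library moved further in both than the other LMF libraries. In it 18 of 22 costimulation members lay above the mean of the other LMF libraries, and 2 of 12 macrophage markers did. For the medians of these lists that argues against a weaker response. The class II list fell in LMF by fry (adjusted p = 0.0104) and did not pass camera. In that list this library moved less, which a weaker response would also give. A weaker response elsewhere and more mature cells stay open, and the labels name no difference between the libraries of a group.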

How the results depend on the processing

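Only the offsets for GC content and length were chosen after seeing the data. Of 122 called named genes, 118 were called under every one of the 20 alternatives that tested them and 0 changed direction. The calls lost were those of Piezo1 (FPKM, without Control or LMF replicate 4), Pdgfrb (voom and 6 leave-outs), Pf4 (5 leave-outs) and Col1a2 (1 leave-out), and the cause was not tested. The number of genes changed (4845) was 4045 to 5047 in all fits but the test against a 1.5-fold change, which by its construction gave 363 genes, 240 higher and 123 lower, 239 of them at least 2-fold. Genes changed at least 2-fold (387) numbered 113 on log2(FPKM + 1) and 199 on log2(FPKM + 0.1), 2 fits that differ only in the pseudocount. Both tested fewer genes (11533 against 14074) with another test, and what moved the rest of the count was not separated. The count of such genes was 508 with no filter on low counts, 295 with the CPM filter, 264 among protein-coding genes and 388 to 440 without 1 library. H2-Ab1, not called, turned to 0.0156 (log2) with the GC and length offsets, still not called, and the cause was not tested. The replicate numbers do not pair the libraries: same-numbered deviations correlated at 0.0046, 0.028, -0.00080 and -0.013, not every library correlated best with its own number, and the replicate block gave 4774 genes.

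Of the 38 lists 17 moved, 16 to 18 without 1 library, 4 with an estimated correlation, which allows for genes that vary together, and 26 with fry, which does not compare a list with other genes. With an estimated correlation the adjusted p was 0.214 for NRF2 and neutrophil markers, 0.406 for cell cycle, 0.164 for chemokines, 0.0575 for cholesterol synthesis and immediate early genes, 0.168 for costimulation, 0.161 for glycolysis, 0.109 for heat shock, 0.174 for iron, 0.167 for macrophage markers, 0.690 for phagocytic receptors and 0.124 for interferon. With fry these passed: LXR and PPAR-gamma (0.0356), class I (0.0153), class II (0.0104), apoptosis and p53 (4.86e-04), type 2 dendritic cell (0.0497), mast cell (0.00968), monocyte (0.0107), pattern recognition (7.21e-05) and stromal (0.00422). Phagocytic receptors did not pass with the CPM filter (0.0577) or the replicate block (0.0608), and ranged from 0.0297 to 0.18 without 1 library (0.0568 without Control replicate 2, 0.18 without LMF replicate 1). Class I ranged from 0.0367 (without LMF replicate 3) to 0.18 and stromal markers from 0.0303 (without LMF replicate 4, 0.0329 without Control replicate 2) to 0.140. Directions turned in 3 lists that did not pass: B cell markers (0.916 with the replicate block, 0.843 to 0.959 without 1 library), erythroid (0.733 to 0.950) and mechanosensitive channels (0.964 with the block, 0.686 to 0.997). The cause was not tested. At 16592672 counts or more per library, recovery at the smallest simulated fold was 38%. The simulation changed 50 genes at each fold, far fewer than the 4845 called in the data, which makes its adjusted threshold stricter. That recovery may therefore understate what the data can detect, and how many small changes were missed was not measured.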

Other observations

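The KEGG pathways, the genes named from them, Cd163 and Ly6g, which the naming rule does not hold, and the tests of macrophage and neutrophil markers were chosen after their values were seen. Among 239 KEGG pathway names in the deposited table with at least 10 tested genes, 74 passed camera and 26 with an estimated correlation. Of 129 genes of the ribosome pathway none rose and 41 fell (camera adjusted p = 3.10e-04, adjusted p = 0.526 with an estimated correlation), among them Rps4x at -0.26 ± 0.04 (SE) and Rpl7 at -0.20 ± 0.04. Of 70 genes of ribosome biogenesis, the assembly of new ribosomes, 29 rose and 6 fell (camera adjusted p = 0.00281, adjusted p = 0.0774 with an estimated correlation), with Gnl3 and Nop58 at 0.64 ± 0.08 each. Of 42 proteasome genes 19 rose and 1 fell (camera adjusted p = 0.00140, adjusted p = 0.251 with an estimated correlation), with Psmd14 at 0.40 ± 0.05 and Psmd1 at 0.39 ± 0.05. Of 121 spliceosome genes 30 rose and 2 fell (camera adjusted p = 0.0137, adjusted p = 0.0497 with an estimated correlation), with Tra2b at 0.40 ± 0.05 and Srsf3 at 0.28 ± 0.04. Of 16 genes of other glycan degradation 1 rose and 8 fell (camera adjusted p = 0.00510, adjusted p = 0.170 with an estimated correlation), with Engase, the lysosomal mannosidase Man2b1 (-0.44 ± 0.03) and Hexa among the lower ones. Some pathways gave another camera call than the fixed list of like theme. Hippo signalling had 34 of 93 genes higher and 12 lower (camera adjusted p = 0.0252, 0.0635 with an estimated correlation). The lysosome pathway had 17 of 114 higher and 44 lower (camera adjusted p = 0.0268, 0.420 with an estimated correlation). Regulation of actin cytoskeleton had 55 of 161 higher and 31 lower (camera adjusted p = 0.0806). Toll-like receptor signalling had 35 of 82 higher and 15 lower (camera adjusted p = 0.00489, 0.0497 with an estimated correlation). NOD-like receptor signalling had 25 of 53 higher and 8 lower (camera adjusted p = 0.00107, 0.105 with an estimated correlation). Apoptosis had 33 of 76 higher and 15 lower (camera adjusted p = 0.0104, 0.0819 with an estimated correlation), and p53 signalling did not pass (camera adjusted p = 0.457).

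Other splits of the 8 libraries bear on the counts. Of the 35 splits into 4 and 4, only 1, the real one, gave as many genes changed (4845), higher (2464), lower (2381) or changed at least 2-fold (387). That is the smallest share 35 splits allow, and it argues against an arbitrary grouping of these 8 libraries. The highest of the other splits was 0 for each, but mixed splits carry the group difference in their spread, so these values add nothing further. A chance difference between cultures is not excluded, because the labels do not say whether the libraries of a group came from separate cultures. For the number of lists moved even an arbitrary grouping is not excluded, because 2 of the 35 splits, the real one included, gave 17 lists. The splits that kept 3 Control libraries together gave 9 to 17 lists and those that parted them evenly 0 to 3, which points to the group difference carried over in part.

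Of 12 macrophage markers 8 fell and none rose, and of 15 neutrophil markers 9 rose and 1 fell. Both list calls were lost with an estimated correlation (adjusted p = 0.167 and 0.214). The members moved unequally, with 98.61% of the variance of the macrophage markers' log2 changes beyond their standard errors (from Apoe at -1.28 to Cd163 at 0.17) and 95.5% for the neutrophil markers (from Ly6g at -0.72 to Lcn2 at 0.71). Unequal changes exclude neither explanation, because other cells of the culture may express the markers at unequal levels and the standard errors are small. Fewer macrophages or more neutrophils and changed expression within the cells cannot be told apart in these bulk libraries.

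Of 35 cell cycle genes 16 rose and 4 fell, a list call lost with an estimated correlation (adjusted p = 0.406), and more cells in S phase could be one reason. In an outside list of S-phase genes, without those of the cell cycle list, 10 of 33 rose and 2 fell, with a median log2 change of 0.2077, above 99.99% of 10000 random lists of matched expression. Of the 38 outside G2/M genes 7 rose and 1 fell, with a median of 0.08, above 97.2% of the random lists. The random lists were not matched for how far genes vary together, and the cell cycle list had an estimated correlation of 0.19. Both percentiles may therefore overstate the evidence. The medians of the phases differed (permutation p = 9.8e-04, genes not being independent replicates). The result is in line with more cells in S phase, and S-phase genes raised without more such cells stay open.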
